A study of Mus musculus with 18 samples.

How the data were processed

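DNA of single oocytes was digested with MspI, ligated to adaptors, bisulfite converted and amplified by PCR, per the labels' protocols. The submitters' processing notes name BSMAP 2.89 and the mouse build mm9. Per the file headers, each deposited table lists, for every CpG with at least 1 read, the count of all reads and the count of methylated reads, summed over both strands, and the same counts per strand. The methylation ratio in the deposited tables is a fraction from 0 to 1, the methylated count over the total count. Filters applied by the authors are not given in the sources used here. Unmethylated lambda DNA was added to measure conversion, per the labels, and its reads were not analysed here.

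From these counts, CpGs with at least 5 reads on the autosomes and X were kept, and the methylation level of an oocyte was the mean over its CpGs, each weighted equally. CpG density was the number of CpG positions seen in any library within 100 bp on either side, counting the CpG itself. Tiles of 1 kb were counted as covered in an oocyte with at least 3 such CpGs, and were compared where covered in at least 3 SF wild-type, 3 SF knockout, 3 EAF wild-type and 2 EAF knockout oocytes. Group values are means over oocytes. Read totals of a library, chromosome or tile are sums of the counts at its CpGs. A read that spans several CpGs is therefore counted at each of them, and the number of separate reads is smaller. Exact binomial intervals at 95% on an oocyte's reads are narrow and cover counting error only, since PCR copies are not independent molecules.

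The design fixed before the data were examined took the oocyte as the unit of exact permutation tests of group means and of an edgeR quasi-likelihood test per tile, with limma as the alternative. Each library is 1 cell and no animal is named, so oocytes of a group cannot be taken as independent replicates and a group counts as 1 sample. Those planned tests had been computed, and their results seen, when they were set aside for this reason. After Benjamini-Hochberg adjustment neither the permutation tests nor edgeR had called any difference. Among the analyses run, the design named that adjustment for tiles and density classes only. Without it, permutation tests of the other values passed the planned threshold in some contrasts. These were the wild-type stage differences over all CpGs, over autosomes, and in the shares at 20% or below and between 20% and 80%. The SF genotype difference in the excess of the X over the autosomes also passed. For contrasts of single values that rest on the 2 EAF knockout oocytes against 1 other group, the permutation test has too few arrangements to pass its threshold, so the lack of a call there says nothing about the difference. Some other settings that were tried did make calls, among them limma, fits on fewer groups, and an added permutation test that combined both stages. The differences given here are therefore descriptions, and none is claimed to exceed chance. The edgeR step had been run on simulated data for the SF genotype comparison over 1084 tiles. It recovered 49.2% of tiles shifted by 20 points and 98.5% of those shifted by 40 points, and called 5 unchanged tiles. The simulated levels and spread between oocytes were set by hand, so these shares do not give the power on the real tiles. There it called none, even where the SF means differed by -86.2 points. The planned rule for named tiles ranked by p where few passed. It was replaced, after the values were seen, by the 5 largest differences in each direction for both genotype comparisons.

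Alternatives changed the read minimum, the weighting, the tile size and coverage rule, the density radius and the oocytes included. Tiles were selected again whenever an oocyte was left out. Promoters, gene bodies, gene lists and Sall4 itself were not analysed here, because no annotation of mm9 was used, and coordinates were not converted between builds. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and limma 3.58.1.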

Results

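CpG methylation was measured by reduced representation bisulfite sequencing of single mouse oocytes, an assay that reads fragments cut at MspI sites and so samples CpG-rich sequence most heavily. The 18 libraries came from secondary follicle oocytes (SF), 7 of them wild type (WT) and 5 from a Sall4 knockout (KO), and from early antral follicle oocytes (EAF), 4 wild type and 2 knockout. Sall4 encodes a zinc finger transcription factor, and in the knockout its floxed alleles were deleted with Zp3-Cre, which is active in growing oocytes. Read counts summed over CpGs ranged from 464271 in SF WT replicate 3 to 6514029 in SF KO replicate 2. These sums were at least 3688032 in each SF knockout library and at most 3662592 in the SF wild-type libraries. Between 19904 and 204134 CpGs per oocyte had at least 5 reads. The labels list the same postnatal ages for all samples without tying an age to a stage, so the age at collection is not known for any oocyte. The labels name no animal for any oocyte, so each group counts as 1 sample. Tests with the oocyte as the unit were set aside for this reason, so the comparisons below rest on no test, and SDs and ranges describe oocytes, not animals.

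The first question was whether oocytes lacking Sall4 differ in methylation at the early antral stage. Mean CpG methylation was 22.2% ± 1.64 (SD, n = 4 oocytes) in EAF wild type and 10.1% ± 1.37 (SD, n = 2 oocytes) in EAF knockout. The knockout minus wild-type difference was -12.1 percentage points, and the ranges did not overlap, with 19.8% to 23.5% in wild type and 9.10% to 11.03% in knockout. Over the 19 autosomes the differences ran from -7.95 points on chromosome 6 to -17.5 points on chromosome 5. On 883 tiles of 1 kb covered in every EAF oocyte, the difference was -6.77 points.

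**Figure D1:**
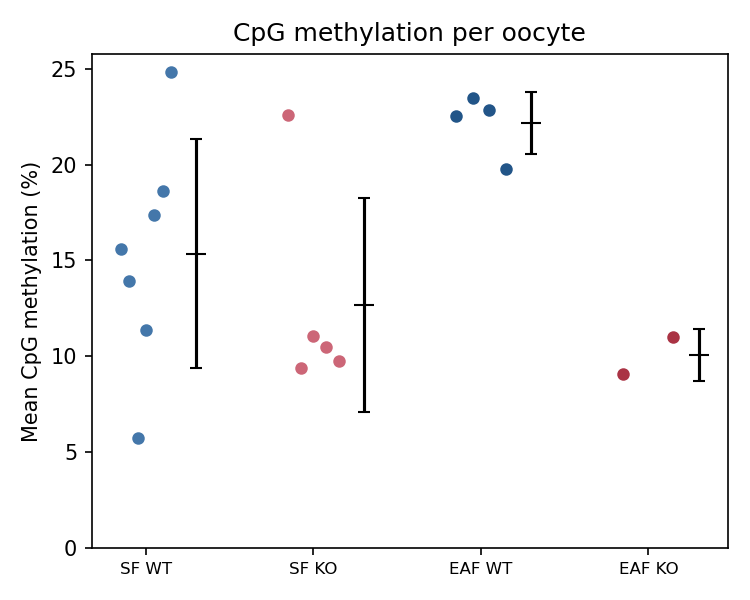
Mean CpG methylation in percent (vertical axis) of each oocyte (points) in the 4 groups, with the mean and SD over oocytes as bars beside them. The 2 EAF knockout oocytes lie at 9.10% and 11.03%, below the 4 EAF wild-type oocytes at 19.8% to 23.5%.

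The gap between EAF genotypes was widest in CpG-poor sequence and narrowed as CpG density rose. CpGs with 1 to 4 CpGs seen within 100 bp had 30.05% ± 1.79 (SD, n = 4) methylation in wild type and 8.08% ± 2.32 (SD, n = 2) in knockout. Those with 5 to 9 had 27.3% ± 1.61 and 13.6% ± 2.86, and those with 10 to 19 had 19.3% ± 1.64 and 11.1% ± 0.526. CpG-dense sequence, with 20 or more, was nearly free of methylation in both, at 1.08% ± 0.203 and 0.526% ± 0.0376. Highly methylated CpGs were fewer in the knockout: 5.52% ± 1.50 of CpGs stood at 80% or above, against 16.1% ± 1.38 in wild type. The share at 20% or below was 85.7% ± 1.60 in knockout and 72.0% ± 2.32 in wild type. With CpGs counted within 250 bp, the difference for 20 or more CpGs was -6.57 points instead of -0.552.

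**Figure D2:**
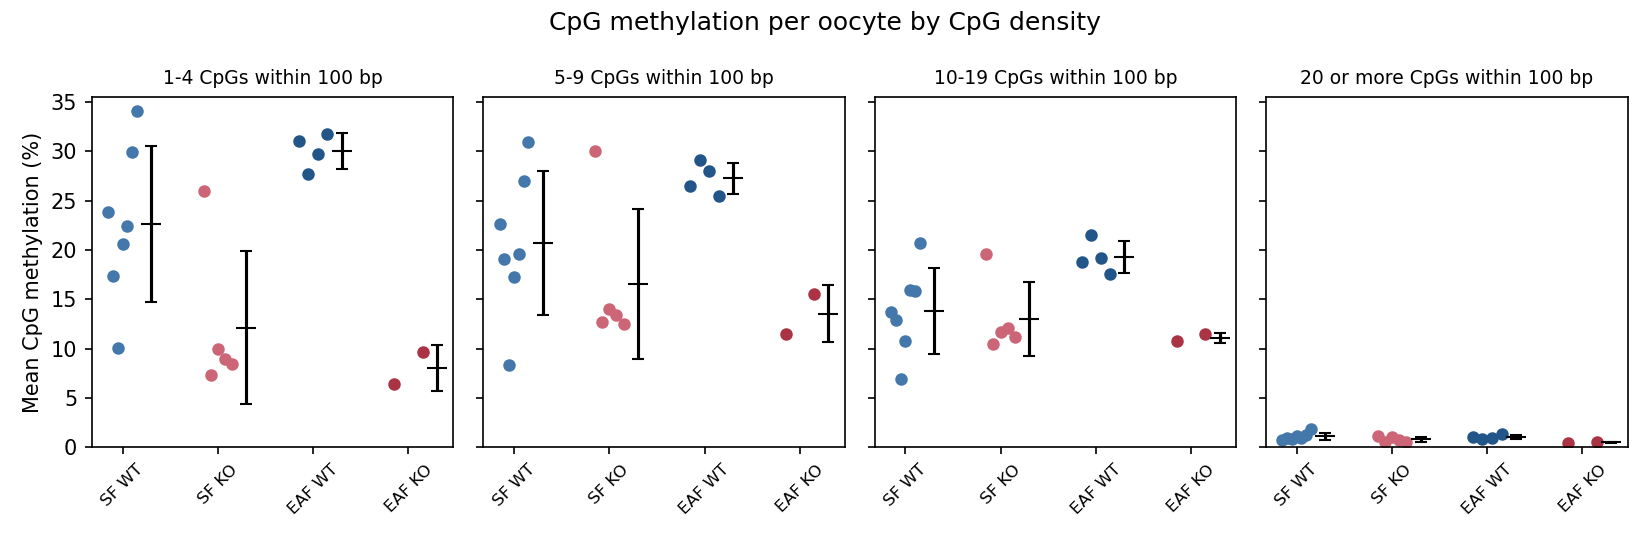
Mean CpG methylation in percent (vertical axis) of each oocyte (points) by the number of CpGs seen within 100 bp, with the mean and SD over oocytes as bars. In the class of 1 to 4 CpGs the EAF groups average 30.05% and 8.08%, while in the class of 20 or more they average 1.08% and 0.526%.

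Among SF oocytes the same genotype comparison gave overlapping values. Mean methylation was 15.4% ± 5.98 (SD, n = 7) in wild type, with a range of 5.76% to 24.8%, and 12.7% ± 5.58 (SD, n = 5) in knockout, with a range of 9.41% to 22.6%. The difference of -2.70 points was smaller than the spread between oocytes. CpG-poor sequence with 1 to 4 CpGs within 100 bp stood at 22.6% ± 7.91 in wild type and 12.2% ± 7.77 in knockout, a difference of -10.5 points that was -13.9 without SF KO replicate 1. That oocyte, at 25.9%, gave the overlap in this class. The other SF knockout oocytes lay at 7.33% to 10.005%, just below the lowest SF wild-type oocyte, replicate 3 at 10.06%. Over all CpGs SF KO replicate 1, at 22.6%, set much of the spread between SF knockout oocytes. Without it the difference over all CpGs was -5.18 points. That difference was -4.30 points without SF WT replicate 3 and -1.12 points without SF WT replicate 7. On the 335 tiles covered in every SF oocyte the difference turned to +2.36 points, and it was -0.207 points weighted by reads and -1.76 points with at least 10 reads per CpG. It was -4.35 points with at least 1 read per CpG and -4.78 points as a mean over all tiles of 1 kb. Counts were also thinned at random to 464271 in every library, keeping CpGs with at least 1 read. The SF means were then 17.0% ± 5.70 (SD, n = 7) in wild type and 12.7% ± 5.54 (SD, n = 5) in knockout.

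Methylation of wild-type oocytes was higher at the early antral than at the secondary follicle stage. The EAF mean of 22.2% lay 6.81 points above the SF mean of 15.4%, with overlapping ranges. Knockout oocytes had 10.1% at the early antral and 12.7% at the secondary follicle stage, a difference of -2.59 points that was -0.112 without SF KO replicate 1 and -1.63 without EAF KO replicate 1. The EAF genotype difference minus the SF genotype difference was -9.41 points. This contrast was -6.92 points without SF KO replicate 1 and -11.0 points without SF WT replicate 7. The oocyte-level test of this contrast, which made no call, was among those set aside. On the 316 tiles covered in every wild-type oocyte the stage difference was 2.29 points.

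The X chromosome had higher methylation than the autosomes in each group. In EAF oocytes the X stood at 32.0% ± 3.05 (SD, n = 4) in wild type and 19.3% ± 2.28 (SD, n = 2) in knockout. In SF oocytes it stood at 24.9% ± 7.30 (SD, n = 7) and 25.3% ± 7.92 (SD, n = 5). The SF knockout value rested on replicate 1, at 39.4%: the knockout minus wild-type difference on the X was 0.383 points with it and -3.13 points without it. That small difference also turned to -1.76 points without SF WT replicate 3 and to -0.0436 points without SF WT replicate 4. In the other direction it was 2.16 points without SF WT replicate 7 and 2.93 points with at least 10 reads per CpG. The excess of the X over the autosomes was 10.2 and 9.59 points in EAF wild type and knockout, and 9.93 and 13.2 points in SF wild type and knockout. It was 17.5 points in SF KO replicate 1. The SF genotype difference in this excess was 3.30 points, 2.23 without that oocyte and 4.00 without SF KO replicate 4. The CpGs of the X and the autosomes were not matched for density, so a different mix of density classes may contribute.

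At single regions, 1084 tiles of 1 kb were covered in enough oocytes of all groups. In EAF oocytes 775 of them had a lower mean in the knockout and 297 a higher one, with a mean difference of -6.15 points. That difference was -4.03 points without EAF KO replicate 1 and -8.32 without EAF KO replicate 2. Tiles were selected again for each omission, so such values mix the oocyte left out with a change of tiles. In SF oocytes 467 were lower and 615 higher, with a mean difference of 0.0679 points. Its sign changed when 1 oocyte was left out and tiles were selected again. It ran from -4.43 points without SF KO replicate 1 to 1.64 points without SF KO replicate 3. The sign also depended on the tiles: the mean difference was -1.35 points over the 3101 tiles covered in enough SF oocytes. It was -2.36 points over 1755 tiles that needed at least 1 CpG. The split of 467 and 615 was counted on the 1084 tiles only and need not hold for other tiles. Coordinates below are those of mouse build mm9, and the genes at these positions were not analysed here.

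Of the 5 tiles with the largest deficit in knockout oocytes, 3 were among the 5 at both stages. Chromosome 7 from 31640001 to 31641000 was at 100% in all 3 covered EAF wild-type oocytes and at 0% in both knockout oocytes. The counts summed over CpGs were 184 and 98. They were as low as 15 on 3 CpGs in EAF WT replicate 1 and 27 on 3 CpGs in EAF KO replicate 1. The same tile stood at 90.5% ± 12.0 (SD, n = 4, summed counts 449) in SF wild type and 4.30% ± 7.45 (SD, n = 3, summed counts 245) in SF knockout. Chromosome 15 from 35047001 to 35048000 was at 79.9% ± 20.9 (SD, n = 3) against 10.3% ± 5.11 (SD, n = 2) in EAF oocytes, and at 69.5% ± 11.8 (SD, n = 3) against 12.8% ± 10.4 (SD, n = 4) in SF oocytes, wild type first. Chromosome 1 from 132497001 to 132498000 was at 90.0% ± 8.85 (SD, n = 3) against 41.2% ± 17.2 (SD, n = 2) in EAF oocytes. At the SF stage that tile stood at 67.8% ± 18.0 (SD, n = 5) against 32.4% ± 13.5 (SD, n = 5). The other EAF tiles of this kind, chromosome 3 from 4584001 and chromosome 4 from 8325001, had 76.8% and 79.6% in wild type and 21.9% and 31.2% in knockout. In SF oocytes the other 2 were chromosome 17 from 12211001, at 71.5% and 31.7%, and chromosome 14 from 114374001, at 71.9% and 35.5%.

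**Figure D3:**
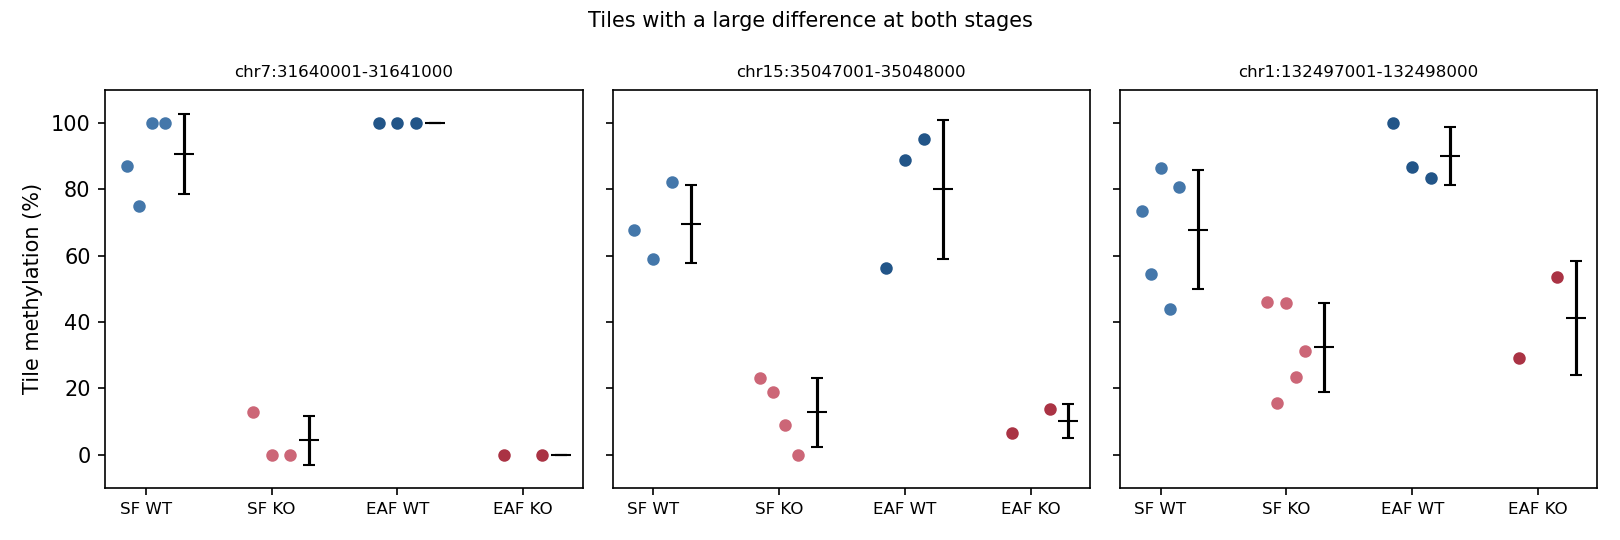
Methylation in percent (vertical axis) of 3 tiles of 1 kb in each oocyte that covers them (points), with the mean and SD over oocytes as bars, by group. On chromosome 7 the EAF wild-type oocytes lie at 100% and the EAF knockout oocytes at 0%.

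Other tiles had higher values in the knockout. In EAF oocytes the largest excess was on chromosome 1 from 18068001 to 18069000, with 0% in 4 wild-type oocytes and 28.6% and 100% in the knockout oocytes. Chromosome X from 148177001 to 148178000 stood at 3.89% ± 6.74 (SD, n = 3) in EAF wild type and 46.7% ± 10.01 (SD, n = 2) in EAF knockout. In SF oocytes the neighbouring tile from 148178001 to 148179000 stood at 9.87% ± 13.3 (SD, n = 5) in wild type and 45.2% ± 17.2 (SD, n = 5) in knockout. The largest SF excess was on chromosome 13 from 6728001 to 6729000, at 24.0% ± 29.0 (SD, n = 5) in wild type and 68.6% ± 4.54 (SD, n = 5) in knockout. Its wild-type oocytes ranged from 4.17% to 74.8%, on counts that summed to 172 over their CpGs. Their mean was 11.4% without SF WT replicate 2. These tiles were picked for the size of their difference among 1084, so their differences overstate what new oocytes would show.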

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

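The tests in this part were all chosen after the values they bear on had been seen. SF KO replicate 1 stood far from the other SF knockout oocytes in 9 of the measures compared, below them in the share of CpGs at 20% or below and above them in the others. Its values were 22.6% over all CpGs, 21.8% on autosomes, 39.4% on the X, 25.9%, 30.1% and 19.7% in the classes of 1 to 4, 5 to 9 and 10 to 19 CpGs, 15.3% of CpGs at 80% or above, 69.9% at 20% or below and 14.8% between. These measures overlap in the CpGs they use, and 10 of 33 comparisons of an oocyte with its group stood out. Chance gives about 1 in 20 for independent oocytes, which overlapping measures and oocytes of unnamed animals need not follow. Incomplete conversion is argued against by its CpG-dense value of 1.19%, close to the highest other SF knockout oocyte at 1.03%. At sites methylated in EAF wild type it had 59.3%, within the 53.8% to 83.9% of SF wild-type oocytes and above the 41.6% to 46.6% of the other SF knockout oocytes. That range alone would allow a wild-type oocyte under a wrong label. The values that follow go against such an oocyte if it held no other DNA. They cannot decide for a wild-type oocyte mixed with DNA of another cell, which could also move them. At CpG-poor sites unmethylated in EAF wild type it had 21.1% and the SF wild-type oocytes at most 9.07%. Its correlations across shared CpGs, which are not independent replicates, were 0.391 to 0.4885 with the 11 wild-type oocytes. Between wild-type oocytes they were higher, at 0.524 to 0.694. With the other SF knockout oocytes its correlations were 0.425 to 0.514, against 0.4505 to 0.535 between those. The other SF knockout oocytes correlated with wild type at 0.392 to 0.514, so such values are not particular to SF KO replicate 1. DNA of another cell may contribute and stays open: its X-linked CpG-dense value of 2.38% lay within the 0.351% to 6.39% of the other SF knockout oocytes, and few CpGs bear on it.

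EAF WT replicate 2 stood apart from its group in the share of CpGs between 20% and 80%, at 15.3%. Reads on CpGs of the Y chromosome, which female cells lack, were listed in all 18 oocytes, from 4 up to 474. Methylated reads made up 5.86% of those on the mitochondrial chromosome in the highest oocyte, SF WT replicate 2, and 3 of 18 oocytes were above 3%. The others above 3% were SF WT replicate 4 at 5.70% and SF KO replicate 3 at 3.58%. SF KO replicate 1 was at 0.406%, and the EAF oocytes ran from 0.052% to 0.374%.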

How the results depend on the processing

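The replicate numbers were not taken to pair oocytes: over tiles, deviations of same-numbered oocytes correlated between -0.113 and 0.0721, with 0 of 13 pairs above 0.1. With the replicate number as a replicate block, as values with no test, the SF and EAF genotype differences were -0.154 and -12.95 points, the wild-type and knockout stage differences 10.5 and -5.93 points, and the stage by genotype contrast -12.8 points. Over tiles these were 2.29, -7.90, 3.85, -10.2 and -10.2 points in the same order. The edgeR and limma fits, which take the oocyte as the unit, are not used as results, and neither is a minimum difference on their calls. The annotation-based results were not run. The equal weighting of density classes and the joint omission of SF KO replicate 1 and the shallow libraries were chosen after seeing the data. The EAF genotype difference in mean methylation stayed between -13.1 and -11.1 points when 1 oocyte was left out. It was -14.2 points as a mean over tiles and -6.77 points on tiles covered in every EAF oocyte, and the cause was not tested. The SF genotype difference ranged from -5.18 to -1.12 points when 1 oocyte was left out, and was -5.21 points without SF KO replicate 1 and the shallow libraries. Its sign changed on tiles covered in every SF oocyte. The stage by genotype contrast over tiles was -6.22 points, -1.76 points without SF KO replicate 1 and -4.11 points without EAF KO replicate 1. Values over tiles with 1 oocyte left out rest on tiles selected again, so the tiles differ too. The knockout stage difference over tiles was -3.21 points and became 1.28 points without SF KO replicate 1, -0.962 points without EAF KO replicate 1, -5.35 points without EAF KO replicate 2 and -2.13 points with at least 1 read per CpG. The SF genotype difference over tiles was 0.0679 points, -0.729 with 100-bp tiles, -0.0765 with 5-kb tiles, and -1.15 and 0.370 with at least 1 and 10 reads per CpG. All 18 oocytes shared 2456 CpGs with at least 5 reads, so most oocyte means rest on different CpGs.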

Other observations

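The tests in this part were all chosen after the values had been seen. CpGs were sorted by their state in EAF wild-type oocytes, each of which was scored on sites set by the other 3. At CpGs at 80% or above in those oocytes, methylation was 83.1% ± 4.82 (SD, n = 4) in EAF wild type, 67.3% ± 9.71 (SD, n = 7) in SF wild type, 48.5% ± 0.433 (SD, n = 2) in EAF knockout and 47.6% ± 6.85 (SD, n = 5) in SF knockout. At CpGs at 10% or below, it was 6.34% ± 1.34 in EAF wild type, 4.22% ± 1.30 in SF wild type, 4.82% ± 1.10 in EAF knockout and 6.59% ± 3.87 in SF knockout. SF KO replicate 1 raised both SF knockout means. It stood at 59.3% in the first class and 13.5% in the second, and the other SF knockout oocytes at 41.6% to 46.6% and 4.46% to 5.29%. The sites are defined on EAF wild-type oocytes, which favours values close to their own class there, high in the first and low in the second.

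The lower methylation of EAF knockout oocytes was set against 3 technical explanations. Unequal counts at the CpGs are argued against, since the difference was -12.8 points after every library was thinned. Thinning was to 464271 counts summed over CpGs, and CpGs with at least 1 read were kept. Without thinning, the same minimum gave -12.6 points. Thinning keeps the expected ratio at each CpG, so it cannot test molecules lost or copied before sequencing. Incomplete conversion in wild type would raise CpG-dense sequence as well, where the difference was -0.552 points. With the density classes weighted equally it was -11.1 points, so the density mix of the CpGs covered does not account for it, although the smaller value on shared tiles leaves other selection open. A difference between animals, their ages, litters or library batches cannot be separated from the Sall4 genotype with these labels. A loss due to the knockout therefore remains an untested hypothesis.

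In the 3 tiles lower in knockout oocytes of both stages, CpGs with a knockout mean lower by 50 points or more numbered 5 of 6 compared on chromosome 7, 10 of 17 on chromosome 15 and 7 of 46 on chromosome 1 in SF oocytes. In EAF oocytes they numbered 3 of 3, 17 of 19 and 14 of 21. The tiles were picked for low knockout means over several CpGs, and sequence differences between the animals were not tested.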
